A study of Mus musculus with 6 samples.

How the data were processed

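The study measured RNA in hepatocytes of 3 Notch-Venus reporter mice after 16 weeks on a NASH diet, per the labels. From each mouse 1 Venus-negative and 1 Venus-positive sample was sorted, and RNA was made into TruSeq mRNA libraries, per the labels' protocols. The submitters' processing notes name STAR, HTSeq, featureCounts and DESeq2 and the builds GRCm38 and mm10; the versions, the role of each tool, the annotation and whether counting used strand are not given in the sources used here. Genes that overlap on opposite strands may therefore not be told apart from their partners.

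The main values are read counts per gene, which the authors deposited without normalization, for 23284 gene symbols. Of these, 16639 had at least 1 count and 6645 had none; every row named a gene. A further table holds a normalized signal: the deposited values equal the counts divided by 1 size factor per sample. It was used only for this check, as was the mean signal per gene in the authors' comparison table, which equals the row mean of the normalized table. That comparison table also gives log2 fold changes and their standard errors, which the authors computed on the log2 scale, a score per gene (the authors' test statistic), and the authors' p-values and adjusted p-values, per the file headers. The ranks of its p-values correlate at 0.999 over genes with a DESeq2 fit without the mouse and at 0.965 with a DESeq2 fit that includes it.

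From the counts, differential expression was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, and the robust quasi-likelihood test of Venus-positive against Venus-negative samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression is given as TMM-normalised CPM, mean ± SD over the 3 mice of a group; an error beside a log2 fold change is its standard error. At the depths here, 3 counts correspond to 0.113 to 0.154 CPM per library, so genes below about 1 CPM rest on few counts; such figures cover counting error only.

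Same-numbered samples come from the same mouse, per the labels, so the mouse numbers pair the samples. The labels state no model, and the main fit has the group alone; the fit with the mouse as a block stands beside a result where it changes a call or moves a count by more than 1.5 times. Deviations from the group mean correlated at 0.307, 0.560 and 0.288 within mice 1, 2 and 3 over genes, and at -0.412 to 0.127 between different mice. The biological coefficient of variation was 0.225 without and 0.137 with the block. Libraries of one group differed by more than sampling noise in every pair, so none was counted as a repeat.

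Gene lists were fixed before the data were examined, 19 of pathways, zones and functions and 7 of cell type markers. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives, adjusted over the 23 lists tested. The estimated correlation comes from these 6 libraries alone, which leaves camera little power. A list not called with it may still have moved. The current symbols G6pc1, Etnppl, Msmo1, Pkm, Spink1, Ccn1, Ccn2, Ajuba, Adgre1, Ighm, Igkc, Ly6g, Hbb-bs and Hbb-bt and the 13 genes encoded in mitochondrial DNA did not match a row under these names. Of these, G6pc1, Ccn1 and Ccn2 were tested under their older symbols G6pc, Cyr61 and Ctgf, and the others were not analysed here. The Venus transgene was not analysed here. Genes named in the text are the tested Notch targets, the 10 largest increases and 10 largest decreases among genes that passed, had a mean of at least 5 CPM and moved the same way in all 3 mice (150 and 336 genes qualified), and in each other list the 4 members with the smallest p. Of the genes this rule names, 3 are not reported here. Other list members were named after their values were seen.

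Gene coordinates are those of the whole gene, introns and untranslated regions included, 1-based on GRCm38 from a GENCODE annotation; 107 of 109 named genes matched by symbol, and those given are protein-coding. That annotation may differ from the one the authors counted with.

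The edgeR steps were tested on simulated counts drawn from these libraries' means and sizes and the dispersions of the blocked fit. In 5 simulations 200 genes were changed, beside a shifted list. With a mouse effect (SD 0.3 on the log2 scale), a log2 change of 1 was recovered for 12.0% of genes without the block and 68.2% with it, and a log2 change of 2 for 85.6% and 95.6%. The false discovery rate was 0.781% without and 12.9% with the block. Without a mouse effect it was 10.2% and 13.1%, so it exceeded the nominal level in 3 of these 4 settings. In the data the blocked fit called 2553 of 12286 genes, far more than were changed in the simulations. The rate depends on the share of changed genes, so these rates need not hold for the data. Unchanged lists were called 0 times, and the shifted list was found in 5 of 5 simulations. Simulated genes varied independently of each other, so this does not test list calls where members vary together. In the data the estimated correlation within a list ran from -0.00373 (Notch receptors) to 0.803 (cholangiocyte markers).

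Alternatives chosen before the data were examined were the mouse as a block, RLE normalization, no filter and a filter of 1 CPM in 3 samples, a fit that is not robust, leaving out each library and each mouse, DESeq2 1.42.0 with and without the block, limma-voom, a log2 fold change of at least 1, and for lists an estimated correlation, fry and lists without shared genes. Chosen after seeing the data were fry with the block, list medians with the GC and length trend removed and, for the blocked count, RLE normalization, no filter, a log2 fold change of at least 1 and leaving out each mouse. GC content and transcript length trends were fitted with mgcv 1.9.3.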

Results

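Hepatocytes came from 3 Notch-Venus reporter mice, in which cells with Notch signalling make the yellow fluorescent protein Venus. The mice had eaten a diet that induces nonalcoholic steatohepatitis (NASH) for 16 weeks. The hepatocytes of each mouse were sorted by flow cytometry into Venus-negative and Venus-positive cells, which gave 6 mRNA libraries, 3 per group. Counts assigned to genes totalled 22185456, 19494355 and 20427273 in the Venus-negative libraries of mice 1, 2 and 3, and 20881847, 20050077 and 26561732 in the Venus-positive libraries. Between 14462 and 15185 genes had at least 1 count in a library. The albumin gene Alb was the most abundant gene in every library, at 6.73% to 8.09% of counts in the Venus-negative group and 5.54% to 6.75% in the Venus-positive group. The first principal component held 56.9% of the variance between libraries and placed the Venus-positive library of each mouse above its Venus-negative library. The libraries of mouse 2 lay highest on it within each group, at -4.87 and 65.3.

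The comparison addressed how hepatocytes with Notch reporter activity differ from reporter-negative hepatocytes of the same livers. Of 20 tested genes of the pericentral zone, the hepatocytes around the central vein, edgeR called 16 lower in Venus-positive cells. Among them, glutamine synthetase (Glul) fell 5.94-fold, from 4495 ± 949 to 757 ± 239 normalised CPM (mean ± SD, n = 3 mice). Of 21 genes of bile acid synthesis and transport 6 fell, and 14 with the mouse as a block in the model. Of 28 hepatocyte identity genes 7 fell, and 16 with the block, and none of either list rose. With an estimated correlation camera called 0 lists, and the adjusted p was 0.505 for the pericentral, bile acid and hepatocyte identity lists each. The unadjusted p of that camera test was 0.0262, 0.154 and 0.118 for these lists. It has little power, as the correlation is estimated from 6 libraries. The β-tubulin gene Tubb2b rose 8.33-fold, from 1.33 ± 0.355 to 11.1 ± 3.37 CPM, and the scaffold protein gene Ahnak rose 4.33-fold, from 11.4 ± 2.75 to 49.3 ± 15.9 CPM. Markers of cholangiocytes, the epithelial cells of the bile ducts, had a median log2 fold change of 2.56 over 19 tested genes. In edgeR 0 of them passed without the block and 18 rose with it, and camera with an estimated correlation gave an adjusted p of 0.571. Only 8 of the 19 had at least 1 CPM in all 3 Venus-negative libraries, and bile duct cells in the sort remain a possible source.

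Of 12286 genes tested with edgeR's quasi-likelihood test, 532 changed at a Benjamini-Hochberg adjusted p under 0.05. Of these, 173 were higher and 359 lower in Venus-positive cells, and all 532 moved the same way in each of the 3 mice. They were picked from the same libraries, so this is not separate evidence. Of all tested genes 29.2% were higher and 28.2% lower in all 3 mice. With the mouse added to the model as a block, 2553 genes changed, 1156 higher and 1397 lower, and 531 of the 532 were among them in the same direction. The count fell whichever library was left out, and fewer samples enter these fits. It was 47, 270 and 174 without the Venus-negative library of mouse 1, 2 or 3, and 41, 75 and 135 without the Venus-positive one. Without mouse 1 edgeR called 0 genes (1895 at an unadjusted p under 0.05; DESeq2 called 426 and limma-voom 0), and without mouse 2 or mouse 3 it called 146 or 167. In the blocked model, leaving out mouse 1, 2 or 3 gave 204, 114 or 3804 genes. Calls of genes given without a tool are those of edgeR.

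Of the 4 tested genes of the Notch target list, Hes1, Sox9 and Spp1 were higher in the Venus-positive cells of all 3 mice. In edgeR with all samples they did not pass without the mouse as a block and passed with it. Hes1, a transcriptional repressor induced by Notch (chromosome 16, 30064384 to 30067796), had 106 ± 25.2 CPM in Venus-negative and 170 ± 37.6 CPM in Venus-positive cells (n = 3). Its log2 fold change was 0.68 ± 0.21 (SE), with an edgeR adjusted p of 0.104 without and 0.00723 with the block. Sox9, a transcription factor of the biliary lineage (chromosome 11, 112782224 to 112787760), had 30.6 ± 8.84 and 72.8 ± 29.5 CPM, a log2 fold change of 1.25 ± 0.36 and an adjusted p of 0.0960 without and 7.39e-04 with the block. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), had 229 ± 230 and 1390 ± 813 CPM, a log2 fold change of 2.60 ± 0.84 and an adjusted p of 0.127 without and 0.00541 with the block. Without the block DESeq2 called Hes1 (adjusted p = 0.0176) and Sox9 (9.35e-04), and edgeR called Spp1 without mouse 2 (0.00593) or its Venus-negative library (0.0438). Over 17 alternatives the adjusted p ran from 3.14e-05 to 0.335 for Hes1, from 1.57e-14 to 0.349 for Sox9 and from 1.28e-13 to 0.361 for Spp1. Nrarp lay near 1 CPM, at 0.852 ± 0.206 and 1.09 ± 1.17 CPM, and its log2 fold change of 0.35 ± 0.77 became -0.038 with the block. Hey1, Hey2, Heyl, Hes5, Hes7 and Dtx1 had too few counts to pass the filter, between 0 for Hes5 and 87 for Dtx1 over the 6 libraries together. In mice 1, 2 and 3 Heyl had 4, 5 and 4 counts in Venus-negative and 7, 22 and 11 in Venus-positive libraries, and Dtx1 had 5, 7 and 5 and then 9, 56 and 5. Fitted with no filter, Heyl had a log2 fold change of 1.29 ± 0.72 (adjusted p = 0.339) and Dtx1 1.75 ± 0.92 (0.313), and Hey1, Hey2 and Hes7 did not pass either.

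As a list, the 4 tested Notch targets had a median log2 fold change of 0.97. Of them Sox9 and Spp1 also stand in the cholangiocyte list, whose median was 2.56, and without genes shared between lists too few Notch targets are left for a test of the list. In edgeR none passed over all genes (3 at an unadjusted p under 0.05; DESeq2 called 2 higher and limma-voom 0), 3 passed when adjusted over the list alone, and with the block 3 passed either way. The list's camera adjusted p was 0.0562, 0.0210 with the block and 0.571 with an estimated correlation. The list was also called with the 1 CPM filter (0.0231) and without the Venus-negative library of mouse 2 (0.0358) or the Venus-positive library of mouse 1 (0.0392) or mouse 3 (0.0313). Among 24 tested Notch receptors, ligands and processing genes none passed in edgeR over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05; DESeq2 called 1 higher and limma-voom 0). With the block 3 of them rose, the receptor gene Notch2 (log2 fold change 0.47, adjusted p = 0.0133), the receptor-cleaving protease gene Adam10 (0.35, 0.0277) and Numbl (1.63, 0.0317). Camera did not call the list (adjusted p = 0.114, and 0.505 with an estimated correlation), and fry with the block called it higher (0.0426). Its median of 0.16 became -0.0079 after the trend on GC content and transcript length was removed.

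**Figure D1:**
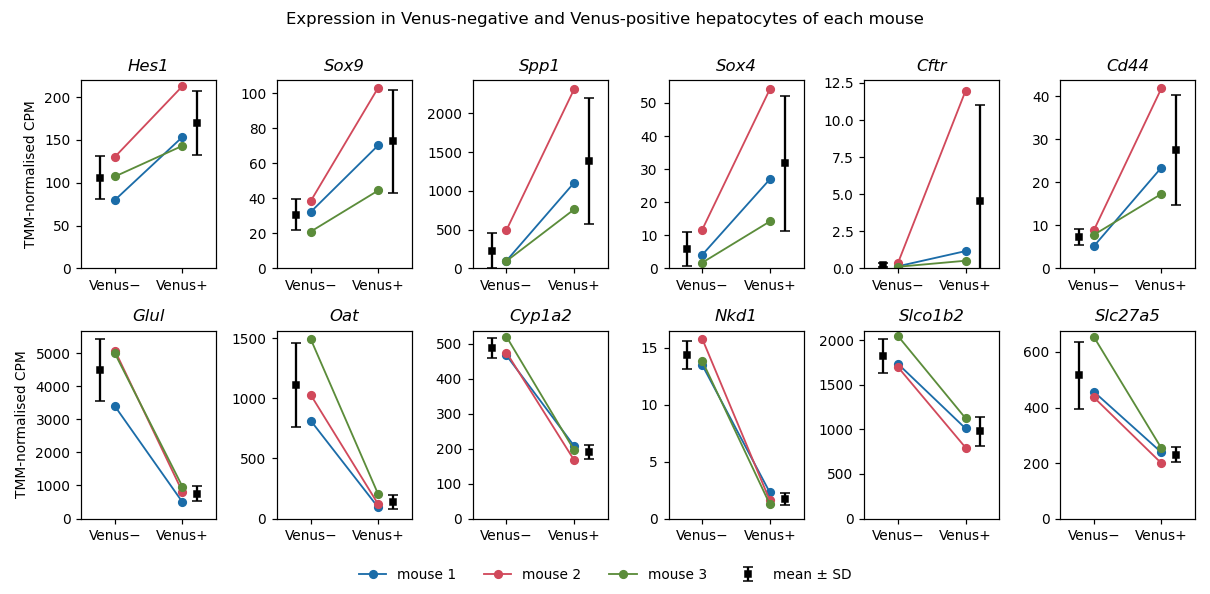
TMM-normalised CPM (linear axes from 0) of 12 genes in the Venus-negative and Venus-positive hepatocytes of each mouse, with 1 line per mouse and black squares for the mean ± SD of the 3 mice. In each panel all 3 lines run the same way: Hes1, Sox9, Spp1, Sox4, Cftr and Cd44 are higher and Glul, Oat, Cyp1a2, Nkd1, Slco1b2 and Slc27a5 lower in Venus-positive cells, and mouse 2 has the highest Venus-positive value of each gene of the upper row.

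Of the 20 tested members of the pericentral list 16 fell and none rose, with a median log2 fold change of -1.51, and 17 fell when adjusted over the list alone. Members that fell included Glul (log2 fold change -2.57 ± 0.28, adjusted p = 0.0102; chromosome 1, 153899944 to 153909723), the Wnt target and feedback inhibitor Nkd1 (-3.07 ± 0.24, 0.00535; chromosome 8, 88521354 to 88594884), the cytochrome gene Cyp1a2 (-1.35 ± 0.12, 0.00874) and the secreted factor gene Lect2 (-1.59 ± 0.17, 0.0102). The ornithine aminotransferase gene Oat (chromosome 7, 132557478 to 132576398) fell 8.10-fold, from 1113 ± 347 to 137 ± 56.8 CPM. The glutamate transporter gene Slc1a2 fell 8.11-fold and the ammonium transporter gene Rhbg 6.16-fold. Camera called the list lower (adjusted p = 1.24e-14), and fry, which tests whether a list moves on balance one way, gave 0.0110. With an estimated correlation the camera adjusted p was 0.505.

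Among 19 tested markers of the periportal zone, at the opposite end of the lobule, none passed in edgeR over all genes (11 at an unadjusted p under 0.05; DESeq2 called 1 higher and 8 lower and limma-voom 0), and the median log2 fold change was -0.33. Adjusted over the list alone 2 rose and 8 fell. With the block the cadherin gene Cdh1 and Hsd17b13 rose, and Sdhd and the urea cycle genes Asl (log2 fold change -0.46) and Otc (-0.61) fell. Hsd17b6 (-1.12) and the urea cycle gene Ass1 (-0.57) did not pass with or without the block. Camera called the list lower (adjusted p = 0.00101, and 0.505 with an estimated correlation). Its median was no lower than the -0.42 of the hepatocyte identity list, so the fall is not shown to be particular to periportal genes.

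Of 28 hepatocyte identity genes 7 fell and none rose (17 fell when adjusted over the list alone), and with the block 16 fell. The nuclear receptor gene Nr1i3 fell 2.46-fold from 113 ± 17.3 to 45.9 ± 11.4 CPM, the organic anion transporter gene Slco1b2 fell 1.87-fold from 1827 ± 192 to 977 ± 167 CPM, and the asialoglycoprotein receptor gene Asgr1 and the apolipoprotein gene Apoa2 fell 1.59-fold and 1.62-fold. The median log2 fold change of the list was -0.42 (camera adjusted p = 5.28e-08, and 0.505 with an estimated correlation). Of 21 genes of bile acid synthesis and transport 6 fell and none rose (12 fell when adjusted over the list alone), and with the block 14 fell. Slc27a5, which activates bile acids for conjugation, fell 2.24-fold from 516 ± 120 to 230 ± 27.9 CPM. Cyp27a1, which starts the alternative pathway of bile acid synthesis, fell 1.93-fold, and the sterol exporter gene Abcg5 1.68-fold. This list had a median of -0.75 (camera adjusted p = 3.60e-07, and 0.505 with an estimated correlation). In the same libraries the 19 tested cholangiocyte markers had a median of 2.56; in edgeR 0 of them passed without the block (10 at an unadjusted p under 0.05; DESeq2 called 5 higher and limma-voom 0) and 18 rose with it, and the camera adjusted p of that list was 0.571 with an estimated correlation.

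Of 24 genes of fatty acid oxidation and its regulator Ppara 2 fell, Acaa1b (log2 fold change -0.83 ± 0.14, adjusted p = 0.0287) and Vnn1 (-0.60 ± 0.13, 0.0428), and none rose. Adjusted over the list alone 13 fell, and with the block 13 fell, Ppara (-0.50, blocked adjusted p = 0.0239) among them. The list's median was -0.41 (camera adjusted p = 1.25e-06, and 0.505 with an estimated correlation). Camera compares a list with all other tested genes. The hepatocyte identity list had a median of -0.42, so this fall is not shown to be particular to fatty acid oxidation. Of 26 genes of lipogenesis and lipid storage only Mogat1 fell (-1.26 ± 0.22, 0.0296), 5 fell when adjusted over the list alone, and 11 fell with the block, including Thrsp (-0.96) and Fads2 (-0.44). Plin4 had -0.80 with the block and did not pass. The median was -0.30 (camera adjusted p = 0.00101, and 0.571 with an estimated correlation), and without mouse 2 the camera adjusted p was 0.0990. This median too was no lower than that of the hepatocyte identity list. Of 22 genes of cholesterol synthesis Ebp fell (-0.72 ± 0.15, 0.0423), alone also when adjusted over the list alone, and with the block 6 fell, including Insig1 and Tm7sf2. That list was not called with all samples (camera adjusted p = 0.114), and was called lower without mouse 3 (0.00237), its Venus-positive library (0.00592) or the Venus-negative library of mouse 1 (0.0377). Of 14 glycolysis genes the regulator Pfkfb3 fell (-0.72 ± 0.10, 0.0192), also when adjusted over the list alone. With the block Hk1 rose (1.46) and Ldha also fell (-0.48), while Aldoa (0.31) did not pass. The glycolysis list was not called (camera adjusted p = 0.847), with a median of 0.062 and a camera direction below 0.

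Among genes with a mean of at least 5 CPM, the 10 largest increases included Tubb2b (log2 fold change 3.06 ± 0.30, adjusted p = 0.0102), Fam102b, the mitochondrial carrier gene Slc25a24, Olfm2, the Rag GTPase gene Rragd, the desaturase family gene Fads3, the ubiquitin-like modifier gene Ubd, the β-arrestin gene Arrb1 and Ahnak. Their log2 fold changes ran from 3.06 in Tubb2b down to 2.11 in Ahnak. Ubd was the most abundant of them, at 17.0 ± 8.46 and 80.3 ± 19.9 CPM. The largest decrease was in Cfd, which encodes complement factor D (-3.93 ± 0.61, 0.0308; 19.4 ± 10.8 to 1.25 ± 0.803 CPM). The 10 largest decreases also held the pericentral genes Nkd1, Slc1a2, Oat and Rhbg, the cytochrome genes Cyp2c37 (-3.34) and Cyp2c50 (-2.96), AW549542 (-3.11), Olig1 (-2.63) and the organic cation transporter gene Slc22a3 (-2.62). Cyp2c37, Cyp2c50 and Tubb2b have near-identical paralogs or pseudogenes, so their separate values are uncertain.

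All 19 tested cholangiocyte markers had a positive log2 fold change. In edgeR none passed over all genes or adjusted over the list alone without the block (10 at an unadjusted p under 0.05; DESeq2 called 5 higher and limma-voom 0), and 18 rose with it; Slc10a2 (log2 fold change 0.15) did not. The chloride channel gene Cftr (chromosome 6, 18170687 to 18322768) had 0.211 ± 0.148 CPM in Venus-negative and 4.55 ± 6.44 CPM in Venus-positive cells, with 1.17, 12.0 and 0.515 CPM in the Venus-positive cells of mice 1, 2 and 3. The transcription factor gene Sox4 had 5.86 ± 5.23 and 31.7 ± 20.4 CPM (log2 fold change 2.57 ± 0.17 with the block, adjusted p = 4.84e-04), and the keratin gene Krt19 stayed at or below 3.70 CPM in every library. Camera called the list higher (adjusted p = 2.01e-05, 1.68e-10 with the block, and 0.571 with an estimated correlation). Its median was 2.42, 2.22 and 1.49 in mice 1, 2 and 3. List medians per mouse, here and below, are of differences in log2 CPM, with a small count added before the log. The list median of 2.56 is of edgeR fold changes, a different measure, and lies above the value of each mouse.

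Markers of stellate, endothelial and macrophage cells moved in different directions in the 3 mice. Stellate cell and fibroblast markers (15 tested) had a median log2 fold change of 0.064, with 1.49, -0.16 and -0.51 in mice 1, 2 and 3. Endothelial markers (19 tested) had 0.17, with 1.06, -0.028 and -0.30, and macrophage and Kupffer cell markers (20 tested) had -0.17, with 0.44, -0.25 and -0.43. The 5 tested lymphocyte markers had -0.34. In edgeR none of these genes passed over all genes or adjusted over the list alone (0 stellate, 2 endothelial, 1 macrophage and 0 lymphocyte markers at an unadjusted p under 0.05; DESeq2 called 1 macrophage marker higher and 1 endothelial marker higher and 1 lower, and limma-voom 0), and with the block Gpnmb (macrophage list, 1.38) and Bmp2 (endothelial list, 0.74) rose. Other members with the smallest p were Rgs5 (2.63 ± 1.11), Tagln (-0.81), Reln (0.43), Bgn (0.49), Marco (-1.64), Ctss (-0.54), C1qc (-0.44), Stab2 (-0.67), Pecam1 (0.51), Egfl7 (0.43), Gzmb (-0.39), Nkg7 (-0.57), Cd8a (-0.34) and Ptprc (-0.24). With all samples camera called none of the 4 lists (adjusted p = 0.536, 0.451, 0.847 and 0.279, for stellate, endothelial, macrophage and lymphocyte markers). Without the Venus-negative library of mouse 3 it called the endothelial (6.01e-04) and stellate (0.00949) lists higher, without mouse 3 the endothelial list (0.0122), and without the Venus-positive library of mouse 1 it called the lymphocyte list lower (0.0458). None of the 11 neutrophil markers found among the deposited genes had enough counts to be tested. Only 2 of the 9 erythroid and platelet markers found among the deposited genes were tested: the haem synthesis gene Alas2 fell 2.33-fold from 109 ± 27.2 to 46.6 ± 7.98 CPM (adjusted p = 0.0267) while Itga2b had a log2 fold change of 0.13.

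**Figure D2:**
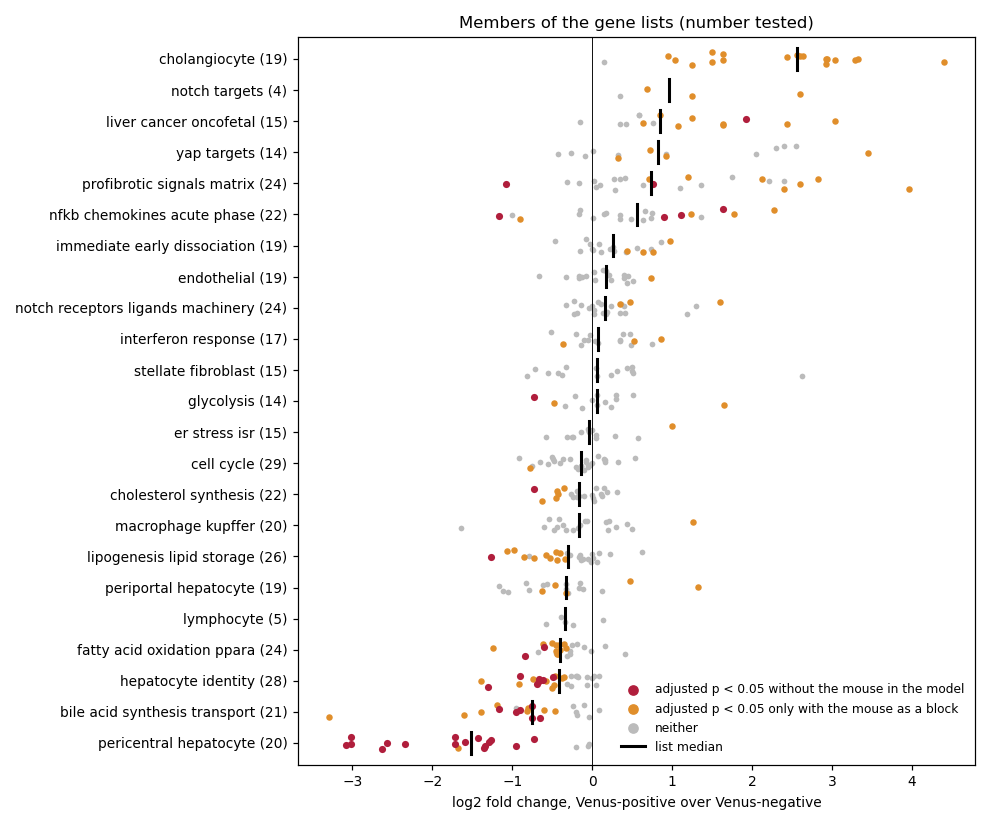
Log2 fold change (Venus-positive over Venus-negative, horizontal axis) of every tested member of each gene list, with the number tested in brackets; dark red points passed an adjusted p under 0.05 without the mouse in the model, orange points only with the mouse as a block, grey points neither, and black bars mark medians. The cholangiocyte list has the highest median, 2.56, with 18 of 19 members in orange, and the pericentral list the lowest, -1.51, with 16 of 20 members in dark red.

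Of 15 tested genes tied to liver cancer and fetal liver 1 rose, the hyaluronan receptor gene Cd44 (log2 fold change 1.92 ± 0.37, adjusted p = 0.0440; 7.27 ± 1.91 to 27.5 ± 12.8 CPM; chromosome 2, 102811141 to 102901665). Adjusted over the list alone 4 rose, and with the block 9 rose, including S100a11 (1.13), Igf2bp2 (0.62), Sox4 and Sox9. The list's median was 0.85 (camera adjusted p = 4.90e-04, and 0.570 with an estimated correlation). Of its 22 members 5 stand in another list too, and its cholangiocyte markers were among those that rose with the block.

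Of 24 tested genes of profibrotic signals and matrix, the laminin gene Lamc1 rose (log2 fold change 0.76 ± 0.13, adjusted p = 0.0281) and the hedgehog ligand gene Ihh fell (-1.08 ± 0.24, 0.0476). Adjusted over the list alone 4 rose and 1 fell. With the block 8 rose, including the galectin gene Lgals3 (2.24, blocked adjusted p = 0.00714), Spp1, Tgfb2 and Tgfb3, and 1 fell; the growth factor gene Pdgfc (1.05) did not pass. The median was 0.73 (camera adjusted p = 4.90e-04, and 0.505 with an estimated correlation; fry with the block 0.0426). Of 14 tested YAP pathway genes none passed in edgeR over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05; DESeq2 called 2 higher and limma-voom 0), and with the block 4 rose, Cyr61 (0.97), Ankrd1, Lats2 (0.32) and Tead1 (0.70), while Dlc1 (0.30) did not pass. This list had a median of 0.82 and a camera adjusted p of 0.0602, 0.0242 with the block and 0.686 with an estimated correlation. It was called without mouse 3 (0.0398), its Venus-positive library (0.0173), the Venus-negative library of mouse 2 (0.0346) or the Venus-positive library of mouse 1 (0.0287). Over the 12 members with a value for GC content and length the median was 0.53, and 0.27 after that trend was removed.

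Of 22 tested genes of NF-κB signalling, chemokines and the acute phase 3 rose: the NF-κB subunit gene Relb (3.10-fold, from 3.28 ± 1.37 to 10.2 ± 2.43 CPM, adjusted p = 0.0392), the macrophage growth factor gene Csf1 (2.16-fold, 0.0407) and the apoptosis inhibitor gene Birc3 (1.87-fold, 0.0462). The acute phase gene Saa3 fell 2.24-fold (0.0398). Adjusted over the list alone 6 rose and 3 fell, and with the block 6 rose and 2 fell. Camera called the list higher (median 0.56, adjusted p = 0.0355, and 0.608 with an estimated correlation), and the call was lost without mouse 1 (0.0818), mouse 3 (0.0729) or the Venus-negative library of mouse 3 (0.0953). None of 17 interferon response genes passed in edgeR over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05; DESeq2 called 1 higher and limma-voom 0); with the block Ifit2 (0.88) and Rsad2 (0.51) rose, Bst2 (-0.38) fell, and Mx2 (-0.53) did not pass. None of 15 genes of endoplasmic reticulum stress passed in edgeR over all genes or adjusted over the list alone (1 at an unadjusted p under 0.05; DESeq2 and limma-voom called 0), and with the block Asns (1.02) rose while Atf4 (0.28), Sdf2l1 (-0.24) and Chac1 (-0.64) did not pass. With all samples neither list was called (camera adjusted p = 0.451 and 0.706), without mouse 3 the interferon list was called (0.0422), and the stress list had a median of -0.038, a mean of 0.017 and a camera direction below 0.

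None of 29 cell cycle genes passed in edgeR over all genes or adjusted over the list alone (5 at an unadjusted p under 0.05; DESeq2 called 1 lower and limma-voom 0), and with the block Cdc20 fell (log2 fold change -0.76). Ccnb2 (-0.92), Birc5 (-0.65) and the replication gene Mcm7 (0.53) did not pass. Camera called the list lower (median -0.14, adjusted p = 0.0355, and 0.583 with an estimated correlation), but not without mouse 1 (0.0895), mouse 2 (0.152), the Venus-negative library of mouse 2 (0.284) or the Venus-positive library of mouse 1 (0.115). Immediate early genes, which cell isolation can induce, were abundant in both groups, with Fos at 1853 ± 498 and 2516 ± 339 CPM. None of 19 passed in edgeR over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05; DESeq2 called 3 higher and limma-voom 0), and with the block Fos (0.47), Fosb (0.86), Ier3 and Klf4 (0.97) rose and Klf6 (0.93) did not pass. Camera called this list higher (median 0.26, adjusted p = 0.0495, and 0.686 with an estimated correlation). That call was lost without mouse 1 (0.0662), mouse 3 (0.211), the Venus-negative library of mouse 1 (0.0645) or mouse 3 (0.342), the Venus-positive library of mouse 2 (0.163) or the filter on low counts (0.0642). In all, camera called 12 of the 23 lists it tested, 5 higher and 7 lower, and 14 with the block. With an estimated correlation it called 0 lists, with 1 at an unadjusted p under 0.05; fry called 1, and 5 with the block (the pericentral and bile acid lists lower and the cholangiocyte, profibrotic and Notch receptor lists higher).

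The authors' deposited table of the same comparison held 1588 genes at an adjusted p under 0.05, 655 higher and 933 lower in Venus-positive cells. It shared 529 of the 532 edgeR calls and 1488 of the 2553 blocked calls, 0 of these in the opposite direction. The largest absolute log2 fold change was 2.77 in the authors' deposited table and 4.41 in edgeR, and whether the authors shrank theirs is not in the labels. DESeq2 without the block, run without shrinkage, gave 0.67 for Hes1, 1.24 for Sox9 and 2.59 for Spp1. Its p-value ranks correlated at 0.999 with the authors'. The authors' smaller sizes for these genes are therefore not read as smaller effects, and sizes are not compared further. In the authors' deposited table Hes1 had a log2 fold change of 0.61 (adjusted p = 0.0178), Sox9 1.03 (9.26e-04), Spp1 0.77 (0.0808), Tubb2b 2.41 (2.38e-16) and Glul -2.27 (3.38e-23).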

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

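The tests of the list values by fry with the mouse as a block, the list medians with the GC and length trend removed, and the alternatives of the blocked count, were chosen after seeing the data. The gene counts changed with the mouse in the model, the test and single libraries; the list calls changed most with an estimated correlation and with fry. Against 532 changed genes (173 higher, 359 lower), edgeR with the replicate block called 2553 (1156 and 1397), DESeq2 1672 (722 and 950), DESeq2 with the block 2178 (972 and 1206), and a log2 fold change of at least 1 left 181 (69 and 112). In the blocked edgeR fit that threshold left 611 genes, more of them higher (411) than lower (200), so the balance of directions depended on the model. DESeq2 without the block also called more members of lists, such as 18 hepatocyte identity genes lower against 7, 14 fatty acid oxidation genes lower against 2 and 8 profibrotic genes higher against 1. RLE normalization, no filter, a filter of 1 CPM, a fit that is not robust and limma-voom kept the count between 431 and 615. Leaving out a library or a mouse gave 0 to 270 genes, 0 to 98 higher and 0 to 172 lower; the 0 came without mouse 1, where 1895 genes had an unadjusted p under 0.05, DESeq2 called 426 and limma-voom 0. Fewer samples enter these fits; no other cause was tested. The blocked count was 2560 with RLE normalization and 2675 with no filter, and 114 to 3804 with a mouse left out (48 to 1904 higher, 66 to 1900 lower).

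Camera called 12 lists, 5 up and 7 down, and 9 to 15 (3 to 7 up, 5 to 8 down) with a library or mouse left out. With an estimated correlation it called 0 up and 0 down (1 list at an unadjusted p under 0.05), and 0 up and 0 down also with the block (2 lists). Fry called 1 list, 0 up and 1 down, and with the block 5, 3 up and 2 down. The block called 14 lists, adding the Notch target and YAP lists, and changed no other list's call. Among 109 named genes it brought 35 past the threshold, and the others kept their side of it. With no filter 7 named genes no longer passed (Slc25a24, Fads3, Ubd, Cyp2c37, Cyp2c50, Cd44 and Ihh), and in limma-voom 7 no longer passed; more genes are tested with no filter. Nrarp changed sign, at -0.038 with the block, -0.17 in DESeq2 with the block and -0.24 in limma-voom, and ran from -0.97 to 0.83 with a library or mouse left out. So did Marco (-2.86 to 0.32), Ptprc (-0.62 to 0.047), Egfl7 (-0.089 to 0.97) and Itga2b (-0.072 to 0.25), none of which passed. As signed -log10 p, lists not called with all samples turned too: macrophage with fry (0.00144) and er stress with fry and the block (0.118), and with a library or mouse left out endothelial (-0.519 to 3.74), er stress (-0.695 to 0.133), glycolysis (-0.716 to 0.359), interferon (-0.0926 to 1.59), macrophage (-0.909 to 1.43) and stellate (-0.949 to 2.31). With the GC and length trend removed, the median of the Notch receptor list moved by more than the SD over mice, to -0.0079 (0.0040 with the block), as did the profibrotic median, 0.59 without the block. The YAP median of 0.82 over 14 members became 0.27, but over the 12 members with a GC value it went from 0.53 to 0.27, within the SD of 0.308. The cause was not tested. Genes below 1 CPM, such as Nrarp and Cftr in Venus-negative cells, rest on few counts.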

Other observations

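The tests of the other cell type lists, of dilution, of the periportal list and of the splits in the blocked model were chosen after the result was seen. A second cholangiocyte list and lists of genes biased to male or female liver were written after a first look at the data, before their genes were looked at.

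Of 18 tested genes biased to male liver, many of which respond to pulsed growth hormone, 13 were lower in all 3 mice and the median log2 fold change was -1.03. In edgeR without the block 0 passed (8 at an unadjusted p under 0.05; DESeq2 called 4 lower and limma-voom 0). With the mouse as a block 7 fell and 1 rose; among those that fell were Elovl3 (-2.28), the cytochrome genes Cyp4a12a (-1.36) and Cyp2d9 (-0.91) and Susd4 (-4.15), and Selenbp2 rose (0.47). These genes were named after their values were seen. Of 7 genes biased to female liver, 2 fell without the block, Cyp2b13 (-2.18) and Hao2 (-1.40); with it these 2 and Acot3 (-0.88) fell and the cytochrome gene Cyp2a4 (1.07) rose. The median was -0.88. The labels do not give the sex of the mice, on which the reading of both lists depends.

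The bile acid transporter gene Slco1a1 (log2 fold change -2.88 with the block) and the bile acid synthesis gene Cyp7b1 (-1.12), both higher in male liver, led to the hypothesis that Venus-positive hepatocytes may have a lower growth hormone response. The test, set before the male-biased list was looked at, asked for at least 70% of its genes lower in all 3 mice. It gave 72.2%, where 28.2% of all genes were lower in all 3 mice, and camera with the block called the list lower (adjusted p = 1.50e-04 over the 3 added lists, 0.196 with an estimated correlation, and fry adjusted p = 0.0270). The female-biased list had a median of -0.88 too (camera adjusted p = 0.0336 without and 0.0632 with the block, and with the block 0.196 with an estimated correlation and fry adjusted p = 0.0122, over the same lists), which goes against a fall particular to male-biased genes, so a general fall of liver enzymes stays open beside this hypothesis.

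The higher cholangiocyte markers could come from a few bile duct cells in the Venus-positive sort or from hepatocytes that express them. More of every other cell type does not account for the whole pattern, though in mouse 1, where the stellate median was 1.49, a share of it stays open: the highest upper quartile of the stellate, macrophage and endothelial lists was 0.463, below the lower quartile of 1.5 of the cholangiocyte list. Of a second list, 76.9% (10 of 13 tested genes) were higher in all 3 mice against 29.2% of all genes, short of the 80% set for cholangiocyte RNA and above the 50% set against it. Of the 19 markers, 8 had at least 1 CPM in all 3 Venus-negative libraries and 6 stand in another list; the most abundant, Spp1, reached 2308 CPM in mouse 2, where Krt19 had 3.70 CPM. How many duct cells remained after the hepatocyte isolation was not measured, and sorting on Venus may not remove those with active Notch. Bulk RNA cannot show which cell a transcript came from, so both sources remain open.

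The fall of pericentral genes was set against technical and sorting explanations. Dilution of hepatocyte RNA by other cells would lower all hepatocyte genes alike, but the lower quartile of the hepatocyte identity list was -0.67, above the upper quartile of -1.19 of the pericentral list. After the trend on GC content and transcript length was removed from the blocked fold changes, the pericentral median was -1.51 (all 20 genes had a value). A larger share of periportal hepatocytes would raise periportal genes, whose upper quartile was -0.16. Their median was -0.33, beside -0.42 for the hepatocyte identity genes, so a small rise relative to other hepatocyte genes stays possible. The periportal values therefore cannot exclude fewer pericentral hepatocytes in the Venus-positive sort. The position of the cells in the lobule was not measured.

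Other splits of the 6 samples into 3 and 3 gave at most 0 genes in edgeR, against 532 for the real one, so 1 of 10 splits gave as many; the other splits had 55 to 873 genes at an unadjusted p under 0.05, 0 to 29 in DESeq2 and 0 in limma-voom. In the blocked model the real split gave 2553 genes and each of the other splits that part all 3 pairs gave 0 (20 to 176 at an unadjusted p under 0.05, 0 to 6 in DESeq2), so 1 of 4 gave as many. Those others swap the 2 samples of 1 mouse. The splits are too few for a share under 0.05.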
